A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

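Total RNA from the Saccharomyces cerevisiae strain MID2extWSC1cyt, in the BY4741 background, was compared with and without caspofungin on 2-colour DNA microarrays, per the labels' protocols. Cells were grown in YEPD at 24 °C, brought to an optical density of 0.2, grown on and split. One part received caspofungin at 15 ng/ml and both parts were collected 2 h later, per the labels' protocols. The labels give the growth before the split as 2.5 h in one text and as 2 h in another. RNA was reverse transcribed with the CyScribe kit, and the RNA of one condition was labelled with Cy5 and that of the other with Cy3, per the labels. The study design, per the labels, had 2 cultures with 2 hybridizations for each, with the dyes exchanged, which makes 4 arrays. Arrays 1, 2 and 4 by the numbers in their titles were analysed here. Array 1 carried the caspofungin RNA in Cy3, and arrays 2 and 4 carried it in Cy5. Arrays 2 and 4 have the same dye orientation and therefore come from different cultures. Array 1 shares its culture with array 2 or with array 4, and the labels do not say with which.

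The deposited table holds 1 log2 value per open reading frame (ORF) and array. It has 6207 ORF rows, each ORF on 1 row, and 2 control rows without values. The scanner, the image analysis, the background correction, the normalization and the filter behind empty cells are not given in the sources used here. The log base was found from the values: 2 raised to each deposited value was a whole multiple of 0.0001, within 0.01 of a step, for 100% of the values on each of the 3 arrays. With natural or base-10 logarithms, or with the sign turned, at most 2.98% of the values of an array met this. The values are therefore read as log2 of ratios that the authors kept to 4 decimals. The medians were −0.24, −0.14 and −0.93 on arrays 1, 2 and 4, so the deposited values were not centred on 0 over the ORFs listed. The centring step and the direction of the ratio are not given in the sources used here.

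The direction was handled by a rule set before the data were examined, as were the gene lists, the tests, the rule for named genes and most alternatives. By that rule, array 1 counts as already turned to the direction of arrays 2 and 4 where it correlates positively with them, which it did. The same positive correlation would also appear if the values were Cy5 over Cy3 on every array and carried a gene-specific dye effect. In that case the caspofungin term and the dye term of the fit exchange places. Signs are therefore given as positive or negative on the deposited scale. Read as caspofungin over untreated, the reading fixed by the rule, a positive value would be higher with caspofungin.

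ORF names were matched to the RefSeq gene table of assembly GCF_000146045.2 (R64), used for names and gene lengths only. Of the ORFs, 5654 matched by locus tag, 57 matched by synonym and 496 were not in that table and kept their systematic names. The gene-wise test was limma (version 3.58.1, in R 4.3.3) on the deposited log2 values, with a caspofungin term and a dye term for the 3 arrays, over the 723 ORFs with a value on every array. This leaves 1 residual degree of freedom per gene, which is the difference between arrays 2 and 4. The moderation gave infinite prior degrees of freedom, so that each gene had the same prior SD of 1.19 and the same standard error of 0.727. That error would be too small with any spread between cultures, since array 1 shares a culture with another array and the fit counts the 3 arrays as independent. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Genes with a fitted log2 value of 1 or more in size and the same sign on all 3 arrays were counted as well, without a test.

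Of 28 gene lists fixed from knowledge of yeast genes, 27 had members on the array design. The list of Ty element rows was to be matched by name or protein description, but no name matched and the gene table holds no descriptions, so it gave no result. The 13 lists with at least 5 genes on all 3 arrays were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 13. Camera with an estimated correlation, camera on ranks and fry were run as alternatives. The estimated correlation and fry both read their statistic on the 1 residual degree of freedom, so a call of any list was nearly out of reach. For the wall mannoproteins the estimated correlation was 0, under the preset 0.01, yet the camera p rose from 0.163 to 0.384. A call lost under either alternative is therefore no evidence against a list, and the preset correlation stays unchecked. Camera gives a direction relative to the other genes, which can differ in sign from a list's median because the median fitted value of the 723 genes was −0.36. The percentile of each list's median was taken among 10000 random lists of the same size from the same genes.

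The genes named were up to 12 with the largest fitted value in each direction among genes called and of the same sign on all 3 arrays. Places left were filled by the largest values of the same sign on all 3 arrays, given as values and not as calls. Up to 4 members of each tested list were added by the same criterion, together with a fixed set of cell wall genes (WSC1, MID2, FKS1, GSC2, SLT2, RLM1, CRH1, PRM5, KDX1, PIR3 and CHS3). The fit was tested on simulated data for the same 723 genes, with 200 genes changed in each of 20 runs. It recovered 10.7% of the changes of log2 1, 87.9% of those of log2 2 and 99.8% of those of log2 3, with a mean of 0.25 false calls per run. The simulated values were independent, normally distributed and centred on 0, with the same change on each array and no shared culture. These shares and false calls therefore do not describe the real fit, in which ADE57 at 2.54 was not called.

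Alternatives covered the dye term, the assignment of arrays to cultures, median centring, equal spread, quantile normalization, the genes admitted, each array left out, array 1 turned the other way, and the thresholds. A loess trend on log2 gene length (span 0.75, degree 1) was removed in alternatives added after the values were seen. Its removal also takes out each array's overall level, as centring does. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Permutation tests used 100000 resamples and bootstrap intervals 2000 draws. The number of arrays limits the precision of every value.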

Results

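The data describe how mRNA levels differed between yeast cells treated with caspofungin and untreated cells of the same culture, in a strain with a chimeric cell wall sensor. Caspofungin is an echinocandin that inhibits the synthase of β-1,3-glucan, the main structural polymer of the yeast wall. By its name, the strain MID2extWSC1cyt joins the extracellular part of the sensor Mid2 to the cytoplasmic part of the sensor Wsc1. Both sensors signal through the cell wall integrity pathway, in which the kinase Slt2 activates the transcription factor Rlm1. The comparison asks which genes respond to 2 h of caspofungin at 15 ng/ml in cells that carry this chimera. The parental strain and the single sensors were not analysed here.

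The 3 arrays differed in how many ORFs they measured and in the width of their values. Array 1 had values for 3748 ORFs, which is 60.4% of the ORFs. Array 2 had 2833 values (45.6%) and array 4 had 855 (13.8%). The SD of the log2 values was 0.809 on array 1, 0.436 on array 2 and 1.55 on array 4. Values of at least 2-fold in size made up 19.7% of array 1, 3.14% of array 2 and 54.4% of array 4. All 3 arrays measured 723 ORFs, and 2335 ORFs had no value on any of the 3 arrays. Array 4 had a value for 25.7% of the 2818 ORFs measured on both array 1 and array 2, and for 4.46% of the 2444 ORFs measured on neither.

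The arrays were positively correlated across genes, which are not independent replicates. Pearson's r was 0.436 between arrays 1 and 2, of opposite dye orientation (Spearman's rho 0.297, 2818 genes). It was 0.394 between arrays 1 and 4, also of opposite orientation (rho 0.457, 745 genes), and 0.347 between arrays 2 and 4, of the same orientation (rho 0.390, 724 genes). Without the tenth of genes with the largest mean, r between arrays 1 and 2 was 0.123. Of the 723 genes on all arrays, 383 (53.0%) had the same sign on each array, 55 positive and 328 negative. The share of positive values on each array would give 36.4%.

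**Figure D1:**
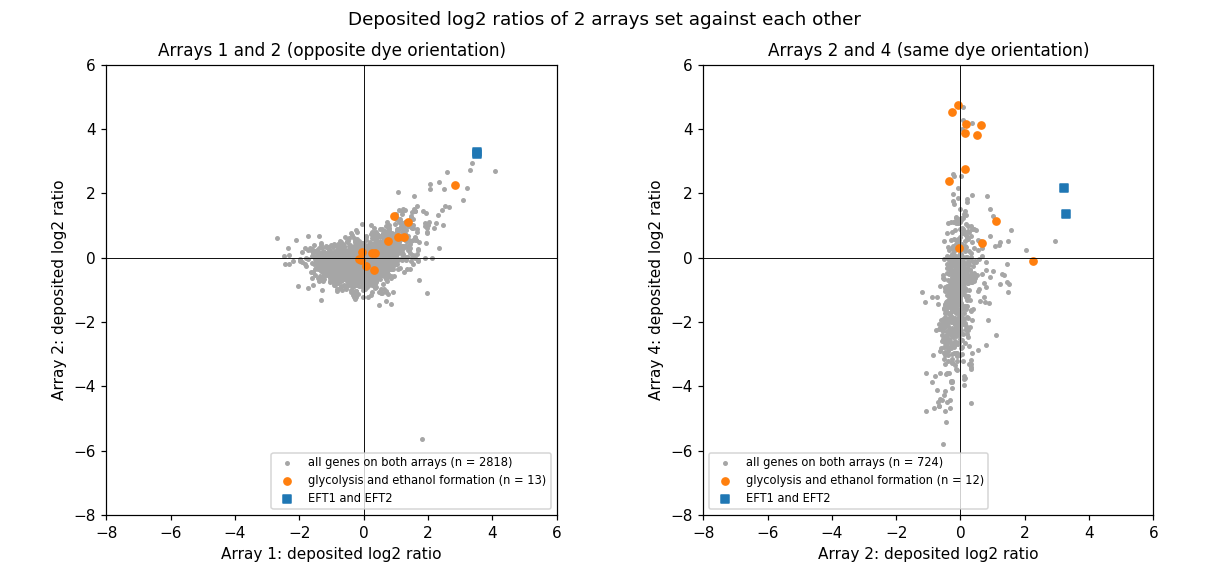
Deposited log2 ratios of array 1 (x axis) against array 2 (y axis) on the left, and of array 2 (x axis) against array 4 (y axis) on the right, with 1 point per gene. EFT1 and EFT2 (squares) lie above 3 on arrays 1 and 2, and most glycolytic genes (orange) lie far higher on array 4 than on array 2.

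Among single genes, those for translation elongation factor 2 stood out. EFT1 (YOR133W) had a fitted log2 value of 3.10 ± 0.73 (SE, 3 arrays; limma adjusted p = 0.0158), with 3.51, 3.22 and 2.17 on arrays 1, 2 and 4. EFT2 (YDR385W) had 2.93 ± 0.73 (SE, 3 arrays; limma adjusted p = 0.0223), with 3.53, 3.29 and 1.37. These near-identical copies encode the same protein, and hybridization cannot tell their transcripts apart, so they amount to a single observation. They were the only 2 of 723 genes called, both positive, and with the sign turned both would be negative. At an unadjusted p under 0.05 there were 23 genes, 9 positive and 14 negative. The dye term of the same fit called 0 genes, with 4 at an unadjusted p under 0.05. No gene was called with arrays 1 and 2 averaged as 1 culture (adjusted p = 0.135 for EFT1 and adjusted p = 0.141 for EFT2 in limma), without array 1, without array 2, without the dye term or with each array centred on its median, among other alternatives. Arrays 1 and 4 averaged as 1 culture gave 12 called genes. Arrays 1 and 2 alone gave 25 among 2818 genes, and 11 over the same 723 genes. With array 1 turned the other way, the values of EFT1 and EFT2 were −0.41 and −0.60.

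None of the other genes with large positive values was called. ADE57, a purine synthesis enzyme, had 2.54 (SE 0.73, limma adjusted p = 0.120). PMA1, the proton pump of the plasma membrane, had 1.94, and VAS1, the valyl-tRNA synthetase, had 1.33. The elongation factor 1 genes TEF1, TEF2 and CAM1 had 1.47, 1.46 and 1.29. Pyruvate kinase CDC19 had 1.82, and the alcohol dehydrogenases ADH1 and ADH2 had 1.46 and 1.34. CDC19 had 0.95 without array 4. For TEF1, TEF2, ADH1 and ADH2 the value rested on array 4, with 4.69, 4.30, 3.81 and 4.19 there against at most 0.74 on the other arrays. TEF1 and TEF2, and ADH1 and ADH2, are pairs of closely similar copies whose spots can cross-hybridize.

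The 12 genes named for large negative values included 7 ORFs that the RefSeq gene table does not list. Such ORFs were 42 of the 723 on all arrays and 15 of the 75 negative ones of at least 2-fold. The 7 were YPR087W (−2.20), YDR327W (−1.71), YOR169C (−1.63), YKL053W (−1.59), YMR294W-A (−1.57), YKL066W (−1.55) and YLR101C (−1.50). Named genes with large negative values were YCX1 (−1.70), EGT2, for a protein of daughter cell separation (−1.63), the myosin light chain gene MLC2 (−1.47) and DID4 (−1.45). YMR321C had −1.69. All 12 values were smaller in size without array 4, from −1.46 for YPR087W to −0.47 for EGT2, and those of YCX1 and YOR169C were −0.74 and −0.69. None was called, and the limma adjusted p of YPR087W was 0.452. In all, 95 genes had a fitted value of at least 2-fold and the same sign on every array, 20 positive and 75 negative. After median centring this count was 61, with 47 positive and 14 negative, and the median of all genes moved from −0.36 to 0.03.

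Cell wall genes went both ways. SED1, a major wall mannoprotein, was positive on each array, with 1.24, 0.83 and 1.91 on arrays 1, 2 and 4, and a fitted value of 1.31 (SE 0.73). GSC2 (FKS2), the alternative catalytic subunit of glucan synthase, was negative on each, with −0.52, −0.51 and −2.95, and a fitted value of −1.12, or −0.51 without array 4. PIR3, a wall protein under Slt2 control, had 0.59, 0.44 and −0.64, with a fitted value of 0.24, or 0.51 without array 4. Neither SED1, GSC2 nor PIR3 was called.

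Of the fixed cell wall genes, MID2, FKS1, RLM1, PRM5 and KDX1 had no value on any of the 3 arrays. SLT2 had a value on array 1 only, 0.22. WSC1 (listed as SLG1, YOR008C) had −0.34 and −0.19 on arrays 1 and 2. The transglycosidase gene CRH1 had 0.88 and 0.02 there, and the chitin synthase gene CHS3 had −1.14 and 0.16. What the probes for WSC1 and MID2 cover is not given in the sources used here, so their values do not check the chimera.

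**Figure D2:**
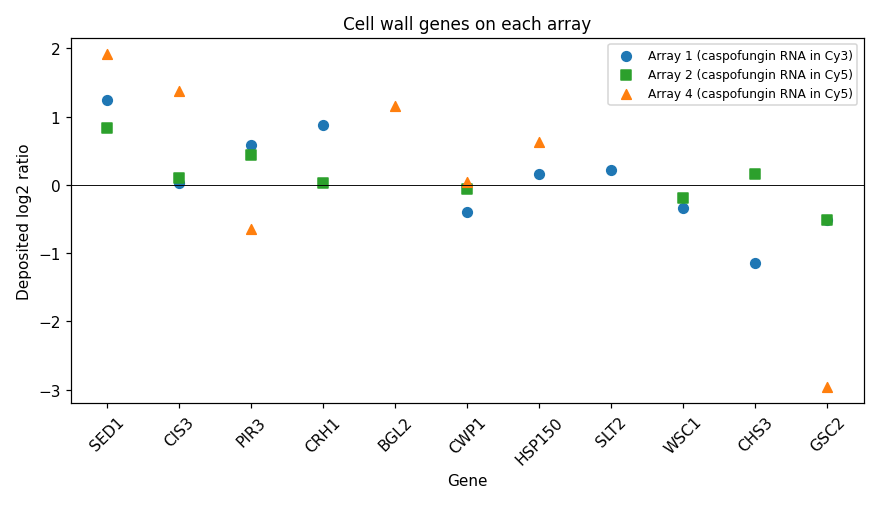
Deposited log2 ratio (y axis) of 11 cell wall genes (x axis) on array 1 (circles), array 2 (squares) and array 4 (triangles), with 1 point for each value present. SED1 is positive and GSC2 negative on all 3 arrays, and 5 of the 11 genes have a value on each.

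As groups, the wall lists did not pass the test. Over 15 settings of the processing, the sign of the median turned in 12 of the 13 tested lists, these included, and was kept in glycolysis alone. In the glucan, mannoprotein and unfolded protein response lists it turned only with array 1 turned the other way. In gluconeogenesis it turned only with the length trend removed from the fit of all 3 arrays. Of the 29 cell wall stress response genes, 7 were measured on all 3 arrays, 4 positive and 3 negative, with a median of 0.11 (camera adjusted p = 0.474), which was −0.01 without array 1 and −0.07 with arrays 1 and 2 averaged. The highest were SED1 and CIS3 (0.39, and 0.07 without array 4), and the lowest were GSC2 and GSR1 (−0.41, and −0.23 without array 4). Of the genes of glucan synthesis and remodelling, 5 were measured on all 3 arrays, 4 positive and 1 negative, with a median of 0.38 (adjusted p = 0.474). With array 1 turned the other way all 5 were negative (median −0.21), and without array 1 the median was 0.08. Among them UTH1 had 0.96. Of the 9 wall mannoproteins, 5 were positive and 4 negative, with a median of 0.11 (adjusted p = 0.474), and DAN1 (−1.23) and FLO9 (−1.07) were at the low end, with −0.59 and −0.48 without array 4. The cell wall integrity pathway had 3 genes on all arrays, 0 positive and 3 negative (median −0.37, or −0.19 on arrays 1 and 2), and chitin synthesis had 0, so neither was tested.

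Glycolysis and ethanol formation was the only list of the 13 tested that was called. Of its 12 genes, 11 were positive and 1 negative, with a median of 1.12, above all of the 10000 random lists (percentile 100). Camera gave an adjusted p = 1.25e-12 at the preset correlation and an adjusted p = 0.916 with an estimated correlation. The second value rests on 1 residual degree of freedom and cannot decide. TDH1, TDH2 and TDH3, and ENO1 and ENO2, are closely similar copies whose spots can cross-hybridize, so the 12 genes are not independent observations. PGI1, phosphoglucose isomerase, was similar on each array, with 1.37, 1.10 and 1.15, while ENO2, enolase, had 0.25, 0.14 and 3.88. The medians of the list's measured members were 0.54, 0.18 and 3.39 on arrays 1, 2 and 4, and the list's median without array 4 was 0.25 over 13 genes (camera adjusted p = 8.84e-05; adjusted p = 0.760 with an estimated correlation). With array 1 turned the other way 9 of the 12 were positive and 3 negative, with a median of 0.56. The call was kept by camera on ranks (adjusted p = 2.78e-06). It was not made with an estimated correlation, as given above, where hardly any list could have been called. Fry, which tests the list against no change and not against other genes, gave an adjusted p = 0.956. It too rests on 1 residual degree of freedom, so this value cannot decide. Of the list's genes, 0 were called when adjusted over the list alone.

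Among translation genes, the cytosolic ribosomal proteins had a median of −0.24 over 78 genes, 19 positive and 59 negative, and were not called (camera adjusted p = 0.678). The list was lower than other genes without array 4 (adjusted p = 0.0237; adjusted p = 0.760 with an estimated correlation) and higher with array 1 turned the other way (adjusted p = 0.00653; adjusted p = 0.865 with an estimated correlation). RPL3 had 1.23, while RPL19B had −1.32, RPS29A −1.25 and RPS21B −1.17. Without array 4 these values were 0.24, −0.61, −0.75 and −0.28. Ribosome biogenesis had 4 positive and 5 negative of 9 genes (median −0.01, adjusted p = 0.474), with medians of −0.47 without array 1, −0.34 without array 2 and 0.37 after median centring, and with NSR1 at 0.43 (0.13 without array 4). All 8 histone genes measured on every array were negative (median −0.61, adjusted p = 0.543). Without array 4 the histone median was −0.29, with array 1 turned the other way it was 0.01 (4 positive and 4 negative), and with the length trend removed it was 0.14 (6 positive and 2 negative). That removal also centres the arrays, and the median of all genes was then 0.12. Single values were −1.09 for HTA2 (−0.36 without array 4), −0.94 for HHF1 (−0.38 without it), −0.80 for HTZ1 and −0.59 for HHO1. After median centring 53 of the 78 ribosomal protein genes were positive (median 0.14), and 3 of the 8 histone genes were positive (median −0.23), while the genes named here kept their signs.

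**Figure D3:**
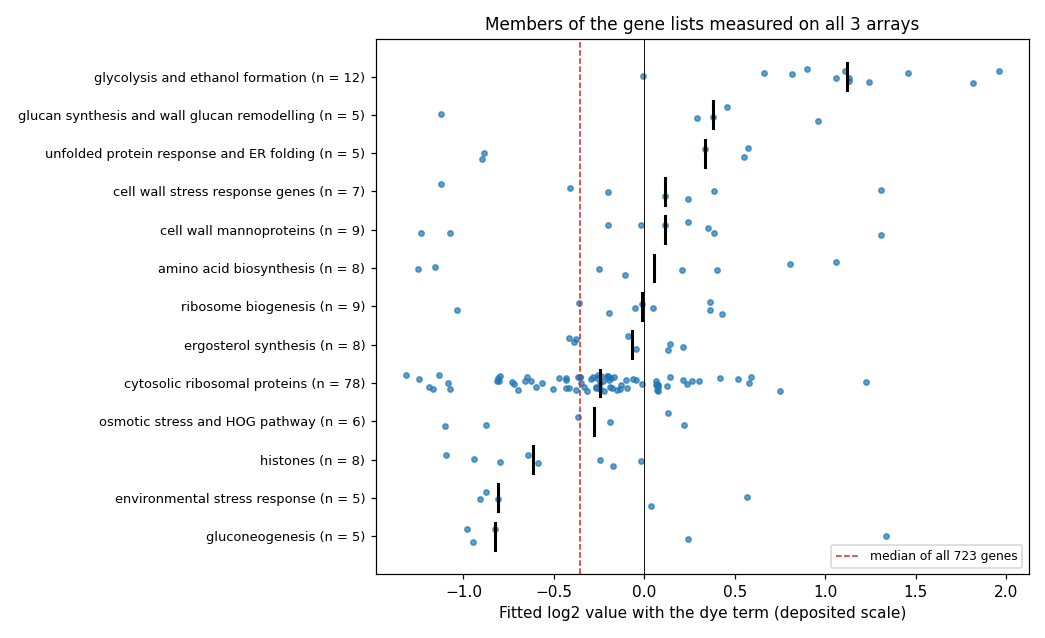
Fitted log2 values (x axis, deposited scale) of the genes measured on all 3 arrays in each of the 13 tested lists (y axis), with 1 point per gene and a black bar at the list's median. The dashed line is the median of all 723 genes, −0.36, and the glycolysis list has its median at 1.12.

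No stress or metabolic list other than glycolysis passed. The 5 induced genes of the environmental stress response had a median of −0.81, 2 positive and 3 negative (camera adjusted p = 0.883), while on arrays 1 and 2 alone the same 5 had a median of 0.08, with 3 positive and 2 negative. Among them were HSP12 at −0.88, TFS1 at −0.81 and GLK1 at 0.57. The 6 genes of osmotic stress and the HOG pathway had a median of −0.28 (adjusted p = 0.897), with GPP2 at −0.19. Gluconeogenesis and growth on non-glucose carbon had a median of −0.83 over 5 genes (adjusted p = 0.883), with JEN1 at −0.98, COX4 at −0.94, CYC1 at −0.83 and ADH2 at 1.34. That median was −0.36 on arrays 1 and 2 alone. With the length trend removed it was 0.13, where the median of all genes was 0.12. In the main fit the list's camera direction was upward relative to other genes, against the sign of its median. The 5 genes of the unfolded protein response and ER folding had a median of 0.33 and a mean of −0.07 (adjusted p = 0.543), with PDI1 at 0.57, SEC61 at 0.55, JEM1 at −0.90 and INO1 at −0.89. That median was 0.18 without array 1 and −0.20 with array 1 turned the other way. Ergosterol synthesis had a median of −0.07 over 8 genes (adjusted p = 0.543), with ERG13 at −0.39, ERG20 at −0.38 and ERG3 at 0.13. Amino acid biosynthesis had a median of 0.05 and a mean of −0.04 over 8 genes (adjusted p = 0.474), with SHM2 at 1.06, GCN4 at −0.25 and TRP4 at −1.25. Its median was −0.19 without array 1 and −0.36 with array 1 turned the other way. Without array 4, SHM2 was at 0.67, TRP4 at −0.16, HSP12 at −0.38, GPP2 at −0.31, ERG13 at −0.20, ERG20 at −0.25, JEN1 at −0.58, COX4 at −0.60, CYC1 at −0.36, ADH2 at 0.38, JEM1 at −0.40 and INO1 at −0.51. Adjusted over the list alone, 0 genes were called in any list.

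The other lists had too few genes on all 3 arrays for a test. The iron regulon had 2 (median 0.57), daughter cell separation 3 (median 0.11), calcineurin targets 2 (median −0.70) and phosphate starvation 2 (median −0.03). Drug efflux had 1 gene, with a negative value, G2/M genes 1, sulfate assimilation 1 (−0.36), and pheromone response and a-specific genes shared 1 (−0.09). Most of these values moved with array 4. On arrays 1 and 2 the calcineurin targets CRZ1 and GSC2 had 0.18 and −0.51, the iron genes SIT1 and FRE1 had 0.92 and 0.88, and the phosphate genes PHO84 and VTC1 had 0.59 and −0.43, while PDR12 of drug efflux had −0.46, CYS3 of sulfate assimilation 0.13 and STE2 of the pheromone response 0.13. G1/S genes had 0 on all arrays. Markers of other cell types or states were nearly absent from the measured ORFs. The alpha-specific genes had no value on any of the 3 arrays, and the meiosis and sporulation list had 1 gene, on arrays 1 and 2, with −0.09 and 0.36.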

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

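The alternatives with arrays 1 and 2 alone over the 723 genes and those with the length trend removed were chosen after the values were seen. The number of genes called was 2 with robust moderation, an adjusted p under 0.10, an added 1.5-fold limit or the sign turned. It was 0 with limma without the dye term (40 at an unadjusted p under 0.05), with arrays 1 and 2 averaged as 1 culture (79), after median centring (29), after centring with equal spread (61), after quantile normalization (208), with genes on array 1 and at least 1 other (45), with array 1 turned the other way (4) and with the length trend removed (22). It was 12 with arrays 1 and 4 averaged, 11 with arrays 1 and 2 alone over the 723 genes, 34 with arrays 1 and 2 alone and the length trend removed, and 23 at an unadjusted p. Leaving out each array, and with it the dye term, for which 2 arrays leave no residual, gave 0 to 25: 0 without array 1, 0 without array 2 and 25 without array 4, where 2818 genes could be tested. The adjusted p of EFT1 ranged from 3.01e-07 to 0.998. With array 1 turned the other way EFT1 was −0.41 and EFT2 −0.60, because the terms for caspofungin and dye exchange. The 95 genes of at least 2-fold became 233 with arrays 1 and 2 averaged, 61 after centring, 43 with equal spread, 178 with genes on array 1 and at least 1 other, 13 with array 1 turned, 28 with arrays 1 and 2 alone over the 723 genes, 44 with the length trend removed, 254 at 1.5-fold, 12 at 3-fold, and 104 to 255 with an array left out. The 1 list called became 5 with genes on array 1 and at least 1 other, 2 with array 1 turned, 2 with arrays 1 and 2 alone over the 723 genes, 5 with these arrays and the length trend removed, 0 with an estimated correlation, 0 with fry, and 1 to 7 with an array left out. The 0 with an estimated correlation and with fry was nearly fixed beforehand by the 1 residual degree of freedom. The median of glycolysis ranged from 0.22 to 1.77 over the settings. The ranges that crossed 0 were −0.36 to 0.44 for amino acid biosynthesis, −0.04 to 0.61 for mannoproteins, −0.07 to 0.50 for cell wall stress, −0.37 to 0.29 for ribosomal proteins, −0.94 to 0.08 for environmental stress, −0.15 to 0.32 for ergosterol, −0.21 to 0.80 for glucan synthesis, −1.29 to 0.13 for gluconeogenesis, −0.87 to 0.28 for histones, −0.45 to 0.23 for osmotic stress, −0.47 to 0.40 for ribosome biogenesis and −0.20 to 0.72 for the unfolded protein response. Without the tenth of genes with the largest mean, r was 0.123 for arrays 1 and 2, 0.246 for arrays 2 and 4 and 0.352 for arrays 1 and 4. Of the named genes' values under the alternatives, 708 kept their call or stayed within the SD between arrays, and 67 moved by more without a call. A further 17 gained a call, 18 lost it and 2 reversed. That SD includes array 4 and is wide where array 4 stands apart. EGT2 (−1.63, SD 2.67) and TRP4 (−1.25, SD 2.61) thus counted as within it at −0.47 and −0.16 without array 4. The 708 is therefore no measure of stability. Other than for the turned array and the numbers of genes tested, the cause of the differences between settings was not tested. Each row of the table as its own feature was not run because no ORF was repeated. Signal over background is not given in the sources used here, so its limit on these values is unknown.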

Other observations

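Of the tests in this part, those that remove the length trend or compare gene lengths, that of unturned dye values and that of a signal of 1 RNA on array 4 were chosen after the result was seen, as were the genes named here from arrays 1 and 2 and array 4. Arrays 1 and 2, of opposite dye orientation, measured 2818 genes in common, and 25 of these were called, all positive (limma without a dye term, adjusted p under 0.05). These calls take array 1 as already turned. Turned the other way, each of the 25 would have opposite signs on the 2 arrays, HAC1 with 4.07 and 2.71 as deposited among them. A dye effect in values that were not turned thus stays open for all 25. If array 1 shares its culture with array 2, which the labels leave open, these calls and the list calls below come from 1 culture and their error covers hybridization only. Besides EFT1 and EFT2 they included ADE3, of folate metabolism (3.02), ADE57 (3.15), HAC1, the transcription factor of the unfolded protein response (3.39), VMA1, a subunit of the vacuolar proton pump (2.64), and CDC48 (2.68). Others were SEC24 of vesicle coats (2.35), STT3 of N-glycosylation (2.31), PMT2 of O-mannosylation (1.74), PMA1 (2.12), the sodium pumps ENA1 (1.95) and ENA5 (2.44), whose near-identical copies cannot be separated, the vacuolar protease PRB1 (1.65), TRP5 (1.82), NAT1 (1.68), NAP1 (1.54) and NPL3 (1.51). ORFs with only a systematic name were YBL005W-A (2.17), YMR046C (2.10), YHL050C (2.06) and YFL067W (1.47). Whether any of them is a Ty element row was not checked. The 25 called genes were long, with a median of 2409 bp against 1152 bp for all genes tested, and 23 of the 25 were longer than that median (permutation p = 2e-05, two-sided by doubling the one-sided share, the smallest this test can give with 100000 resamples). With the length trend removed, 34 genes were called, the 25 among them. Array 4 measured 8 of the 25, and 5 were positive there.

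On the same 2 arrays 7 lists were called with camera at the preset correlation, and 0 with an estimated correlation (adjusted p = 0.760 for each of the 7). The estimated correlation again used 1 residual degree of freedom, so that 0 was nearly fixed beforehand. The glucan synthesis and remodelling list had a median of 0.37 over 18 genes, 16 of them above the median of all genes (adjusted p = 0.00168), led by CWH41 (1.24), UTH1 (1.17) and KRE6 (1.06, from 2.11 on array 1 and 0 on array 2), while GSC2 (−0.51) and KRE5 (−0.68) were lowest. Amino acid biosynthesis had 0.19 over 20 genes (adjusted p = 0.00186), led by ASN1 (1.27) and HIS4 (1.01), and ribosome biogenesis had 0.23 over 34 genes (adjusted p = 0.00186). These values leaned on array 1: the medians of the measured members were 0.51 and 0.14 on arrays 1 and 2 for the glucan list, 0.40 and 0.01 for amino acid biosynthesis, 0.40 and −0.03 for ribosome biogenesis, 0.54 and 0.18 for glycolysis, and 0.45 and 0.08 for the unfolded protein response. Glycolysis had 0.25 over 13 genes, all above the median of all genes (camera adjusted p = 8.84e-05). It was led by PFK2 (2.55, itself called on these arrays), PGI1 (1.23) and PFK1 (1.13), while GPM1, TDH2, TDH3 and TPI1 lay between −0.03 and −0.09. On array 4 PFK2 had −0.11, and TDH1, TDH2 and TDH3 had 4.17, 4.54 and 4.76. The highest members thus differed between arrays 1 and 2 and array 4. The unfolded protein response list was also higher (median 0.29, camera adjusted p = 0.0237). It holds HAC1 at 3.39, while its other genes ran from SEC61 at 0.70 to INO1 at −0.51. How far its call rests on HAC1 was not tested. The ribosomal proteins were lower than other genes (median −0.24, camera adjusted p = 0.0237). After removal of the length trend neither list was called. The unfolded protein response list kept its direction (median 0.20, camera adjusted p = 0.310). The ribosomal proteins turned to the other side (median 0.10, camera adjusted p = 0.500). Cell wall stress response genes were not called (median 0.09, adjusted p = 0.157). The 7 list calls take array 1 as already turned. With it turned the other way in the fit of all 3 arrays, medians were −0.21 for the glucan list (5 genes) and −0.36 for amino acid biosynthesis (8 genes). They were −0.44 for ribosome biogenesis (9 genes) and −0.20 for the unfolded protein response (5 genes). Ribosomal proteins had 0.03 (78 genes) and glycolysis 0.56 (12 genes). That fit held fewer genes of each list and included array 4, so these medians do not show the effect of turning alone. The iron regulon had too few genes there.

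The iron regulon, the genes for iron uptake under Aft1 control, had a median of 0.79 over 11 genes on arrays 1 and 2, against −0.18 for all genes, with 10 of the 11 above that median (camera adjusted p = 8.84e-05; adjusted p = 0.760 with an estimated correlation). FET3 had 1.35 and 0.69 on the 2 arrays, SIT1 1.05 and 0.80, and TIS11 1.68 and 0.25, and array 4 had SIT1 at −0.91 and FRE1 at −0.61. The length trend as the whole cause is argued against, since the median after its removal was 0.79, against 0.04 for all genes (camera adjusted p = 0.000625). The lead over all genes was smaller than before the removal. A property shared by genes for membrane transporters stays open: 26 other plasma membrane transporters had a median of 0.30, a difference of −0.493 from the iron regulon (95% bootstrap interval −0.848 to 0.266; two-sided permutation p = 0.0208), and 21 of them lay above the median of all genes. A difference in iron status between the cultures with and without caspofungin remains a hypothesis, which the open direction leaves unsettled. The estimated correlation cannot decide, because it rests on 1 residual degree of freedom. Whether the preset correlation holds for these genes is therefore unknown.

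EFT1 and EFT2 were far above 0 on arrays of both dye orientations. Their mean on arrays 1 and 2 was 3.39 (SD 0.153) before and 3.31 (SD 0.273) after removal of the length trend. The average trend was small at their length and could hardly have lowered the mean. It therefore does not account for their size, but other effects tied to length were not tested. A dye effect in values that were not turned cannot be told apart from a response to caspofungin, because turning array 1 exchanges both terms by arithmetic, and 0 of the 2 genes were then called for caspofungin. A response to the drug therefore stays among the open explanations.

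The highest values of array 4 belonged mostly to genes with abundant transcripts in growing yeast, among them FBA1 (5.19), TDH3 (4.76), TEF1 (4.69), TDH2 (4.54), TEF2 (4.30), PDC1 (4.22), CDC19 (4.11) and RPL3 (4.00), with TDH1 (4.17) and with ADH2 (4.19), which glucose represses and whose spot can take ADH1 transcripts. On arrays 1 and 2, TDH3 had −0.08 and −0.07. A ratio that depends on spot brightness may be the cause, and it stays open. ORFs outside the RefSeq table, whose status as genes was not checked, lay at −0.759 relative to the others on array 4 (95% bootstrap interval −1.25 to −0.0618), at −0.480 on array 1 and at −0.101 on array 2 (interval −0.160 to 0.00276). A column that holds the signal of 1 RNA and not a ratio stays open too, because the ribosomal proteins had their median at percentile 73.3 of array 4, between the levels set for and against it. A biological difference between the cultures was not tested.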
